A study of Homo sapiens with 9 samples.

How the data were processed

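Small RNA libraries of 9 ovarian cancer cell lines were analysed, 1 library per line. Per the labels, RNA was extracted with the miRNeasy kit and QIAzol, libraries were made with the TruSeq small RNA kit from 1 µg of RNA, and all lines were at 8% oxygen. Sequencing ran on an Illumina NextSeq instrument, per the series' design text. Small RNA kits join adapters to RNA ends and amplify by PCR, so differences in ligation efficiency between miRNAs and duplicate reads remain in the values. For this reason levels were compared between lines for the same miRNA, and the order of different miRNAs within a line is less certain.

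The deposited files hold, per library, whole-number read counts for each mature miRNA arm and hairpin copy, and the authors had not normalized them. Each file has 2822 entries. The submitters' processing notes name the genome build hg19, DESeq2 1.18.1 and R 3.2.2 without a role, and the aligner, adapter trimming and counter are not given in the sources used here. Copies of a miRNA from different hairpins hold nearly equal counts. This was taken to mean that reads were counted at every identical copy, so that the deposited totals exceed the number of reads. Scatter between these copies was not tested, so a division of reads between them is not excluded. In that case the merging below would undercount miRNAs with several copies. Entries of the same name and arm whose totals lay within 20% of each other were therefore merged and represented by the copy with the highest total, which removed 229 entries and left 2593 miRNAs. This choice was made after the files had been seen, and keeping every deposited entry was tried as an alternative. Of the 2593 miRNAs, 1111 had 0 reads in all lines.

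Reads are also uncertain between miRNAs of almost the same sequence. Among 430 miRNAs with at least 90 reads over the 9 lines, stretches of 20 bases from each arm's side of the hairpin were compared. Arms with a stretch equal or differing at 1 base were linked. Linked arms were chained into groups, which placed 126 miRNAs in 43 groups. Members of a group need not be near-identical to each other, and the group of miR-548k holds both arms of miR-548o. Of 124 expressed pairs of directly linked arms, called near-identical here, 26 kept a ratio with an SD under 0.1 on the log2 scale over the lines. These include miR-10a-5p with miR-10b-5p. Another 34 had an SD over 1, as miR-200b-3p and miR-200c-3p did. An alternative with 1 miRNA per group was added after the data were seen.

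Depth ran from 827077 reads in OVCAR-429 to 3480339 in SKOV-3 after merging, and 1 read corresponded to between 0.550 and 1.02 normalized CPM. Folds between 2 lines were given exact 95% conditional binomial intervals and shares Wilson 95% intervals, both covering counting error only. In the rules for high and low miRNAs below, counts under 3 reads were raised to a floor of 3 reads in their library. Where the lower line had 0 reads, the fold given is that of the rule and is a lower bound. Ratios to 1 or 2 reads use the counts as they are, with the fold against the floor beside them. No pair of libraries was alike within sampling noise, the lowest chi-square per degree of freedom between 2 libraries being 486.

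Normalization used the TMM method of edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 as its dependency, and factors ran from 0.489 in SKOV-3 to 1.45 in OVCAR-420. TMM assumes that most miRNAs do not differ between a pair of libraries. Values were expressed as log2 of normalized CPM plus a pseudocount of 1. A miRNA was counted as expressed at a mean of at least 10 normalized CPM, which 395 reached. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.

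The groups were the 9 cell lines as labelled. With 1 library each, no test between lines was possible, so edgeR's quasi-likelihood test was not run and miRNAs were counted by fixed rules of size. A miRNA was high in a line at 4-fold or more above every other line with at least 50 reads, and low at 4-fold or more below every other line, all of which then needed at least 50 reads. A miRNA was variable when its log2 range over the lines was 4 or more. Lines were compared by Spearman's rho across expressed miRNAs, without a p-value. Dixon's test was applied to 33 measures to find single lines that stood apart.

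Lists of miRNAs were fixed before the data were examined, 32 in all. They were the miR-200 family, miR-17/92, miR-106b/25, miR-106a/miR-363, let-7, miR-221/miR-222, miR-143/miR-145, miR-199/miR-214, HOX cluster miRNAs, miR-34/miR-449, miR-371/miR-373, miR-302/miR-367, C19MC, the 14q32 cluster, the Xq27.3 cluster, miR-181, miR-30, miR-29, miR-183/miR-96/miR-182, miR-23/27/24, miR-15/16, miR-424/miR-503, miR-130/miR-301, miR-99/miR-100 with miR-125, miR-224/miR-452, markers of blood cells, muscle, nerve and other organs, hypoxia, squamous and oncogenic singles, and miRNAs of the earlier platinum literature. The more abundant arm stood for each stem, and a list needed 2 members with a mean of at least 1 normalized CPM for a median. Percentiles came from 10000 random lists matched on size and mean level.

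Co-variation of list members over the 9 lines was the mean pairwise Pearson r, tested by shuffling the lines of each member 10000 times (one-sided permutation test), with Benjamini-Hochberg adjustment over 25 lists that had 2 members at a mean of at least 10 normalized CPM. Of 12 planned pairs of miRNAs, 11 had both members at a mean of at least 10 normalized CPM. For these, Pearson's r and Spearman's rho were tested by exact permutation over all 362880 orderings of the 9 lines, two-sided, in place of the 100000 resamples first planned. A pair whose lines fell into separate clusters was to be tested within a cluster only, which applied to 0 pairs at the main setting. Arm ratios used stems with at least 20 reads of both arms together in every line.

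The miRNAs named in the text follow a rule set before the data were examined. It takes per line the 3 high and the 1 low miRNA with the widest gaps, the 10 miRNAs with the highest SD among those at a mean of at least 50 normalized CPM, the 5 most abundant, in each list the most abundant and the widest ranging member, all members of the miR-200, miR-221/miR-222 and hypoxia lists, the planned pairs, and the 5 stems with the widest arm ratio. In the comparisons of lines, miR-223-3p, miR-150-5p and let-7f-5p were chosen after their values were seen.

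Hairpin positions and host genes come from GENCODE 29 on GRCh38, matched by hairpin name, and are given with that build. The files hold no coordinates, and host genes are those on the same strand.

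The rules were tested on simulated counts drawn from the real levels and library sizes. Of 80 miRNAs raised 8-fold in 1 line, 71 were called high, and of 80 raised 16-fold, 80 were. Of 40 lowered 16-fold, 28 were called low. Among 2393 unchanged miRNAs 0 were called in either direction. Apart from the changed miRNAs, every simulated line had the same mean levels with a small added dispersion. The real lines had a median SD of 1.20 on the log2 scale. The 0 calls were therefore nearly fixed in advance and give no error rate for these lines. For the same reason, the counts of raised and lowered miRNAs called do not show what share the rules would find in these lines. The co-variation test called 5 of 200 independent lists and 200 of 200 lists correlated at 0.8. The pair test called 3 of 200 independent pairs and 195 of 200 correlated at 0.9. Both tests were counted here at a threshold of 0.05 without adjustment, and the simulated lists had 5 members. The arm rule called 100 of 100 simulated switches and 0 of 100 stems without one.

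Alternatives fixed before the data were examined were DESeq2 1.42.0 size factors, the library total alone, pseudocounts of 0.25 and 5, no filter or a mean of at least 100 normalized CPM, minimums of 10 and 200 reads, libraries thinned to 827077 reads, the sum of both arms, an arm minimum of 100 reads, and leaving out each line in turn. Beyond those named above, leaving out each line was extended to line-high counts and similarity, and the lines that stood apart were recomputed under both other scalings, after the data were seen. Targets of miRNAs, platinum response and isoforms of miRNAs were not analysed here.

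The explanations weighed for single patterns had tests set partly before and partly after the results were seen, and 3 of these tests were changed after a first result. The test on near-identical arms was first run on 5 pairs, 3 of which compared an arm with itself or a variant entry through an error. It was rerun on 2 distinct pairs and then, with a lower minimum for the opposite arms, on 12. A further test, added last, set the scatter of the ratio over the lines (chi-square) for all 124 near-identical pairs against 10000 random tables with the same totals. The test for mixing of HEY and OVCAR-3 first asked for 3 miRNAs in each direction, which was not reached, and now rests on the upper counting limit of the share. For the test of that pair with 1 miRNA per near-identical group, the outcome set in advance as counting against shared reads was met. The redrawing of miRNAs was added after that, and the reading then changed to open, since the lead was smaller than the spread of the redraws.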

Results

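Small RNA was sequenced from 9 established ovarian cancer cell lines, CAOV-3, HEY, OV90, OVCAR-3, OVCAR-420, OVCAR-429, OVTOKO, SKOV-3 and TOVII2D, all kept at 8% oxygen. The study asked which microRNAs (miRNAs) go with intrinsic platinum resistance. The labels give no platinum response, so no resistant and sensitive sets were formed, and the lines were compared with each other. Each line had 1 library and no replicate, so differences between lines have no replicate check and carry no p-value. Intervals printed with folds and shares are 95% intervals that cover counting error only, since PCR reads without molecular identifiers are not independent molecules.

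The deposited counts summed to between 1133637 in OVCAR-429 and 4068762 in SKOV-3, with a median of 1798001. After identical copies of the same miRNA were merged, the totals ran from 827077 in OVCAR-429 to 3480339 in SKOV-3. The number of miRNAs with at least 10 reads ran from 317 in OVCAR-3 to 466 in CAOV-3. At these depths 3 reads corresponded to between 1.65 normalized CPM (read counts scaled by normalized library size) in CAOV-3 and 3.06 in OVCAR-3. Levels under this floor are not safely told apart from 0, so the fold against the floor is given beside ratios to fewer reads.

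The most abundant miRNA was miR-21-5p, an oncogenic miRNA raised in many carcinomas, with 10.1% ± 4.21 of reads (SD over 9 lines). It was followed by miR-10a-5p with 6.45% ± 4.66 and miR-10b-5p with 6.22% ± 4.44, both encoded within HOX gene clusters. The let-7a-5p share, from the let-7 tumour suppressor family, was 5.83% ± 1.94, and miR-30a-5p held 5.74% ± 3.80 (both SD over 9 lines). The miR-10a-5p and miR-10b-5p sequences differ at 1 base and their counts were nearly equal in every library, so their separate values are uncertain. The leading miRNA differed between lines. It was miR-21-5p in HEY, with 18.5% of reads (Wilson 95% interval 18.4 to 18.6), and in OV90, with 14.5% (14.4 to 14.5). It was miR-10a-5p in SKOV-3, with 13.4% (13.4 to 13.5), let-7f-5p in OVCAR-429, with 7.73% (7.67 to 7.79), and miR-30a-5p in OVTOKO, with 12.5% (12.5 to 12.6). In OVCAR-429 the near-identical let-7a-5p had 63501 reads against 63915 of let-7f-5p, so the order of these 2 is uncertain.

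The first comparison was how alike the lines were over 395 miRNAs with a mean of at least 10 normalized CPM. HEY and OVCAR-3 were the closest pair, with a Spearman rho of 0.876 across miRNAs. OVCAR-429 and SKOV-3 followed with 0.856. OVCAR-420 and TOVII2D were the most distant pair, with 0.517. The mean over the 36 pairs was 0.710 ± 0.0895 (SD). TOVII2D stood farthest from the rest, with a mean rho of 0.592 to the other 8 lines, and SKOV-3 closest, with 0.767. These correlations are across miRNAs, which are not independent replicates. When the miRNAs were redrawn 1000 times, the lead of HEY and OVCAR-3 over the next pair was 0.0202, with a 95% range of -0.0276 to 0.0599, so it was not larger than the spread of the redraws.

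**Figure D1:**
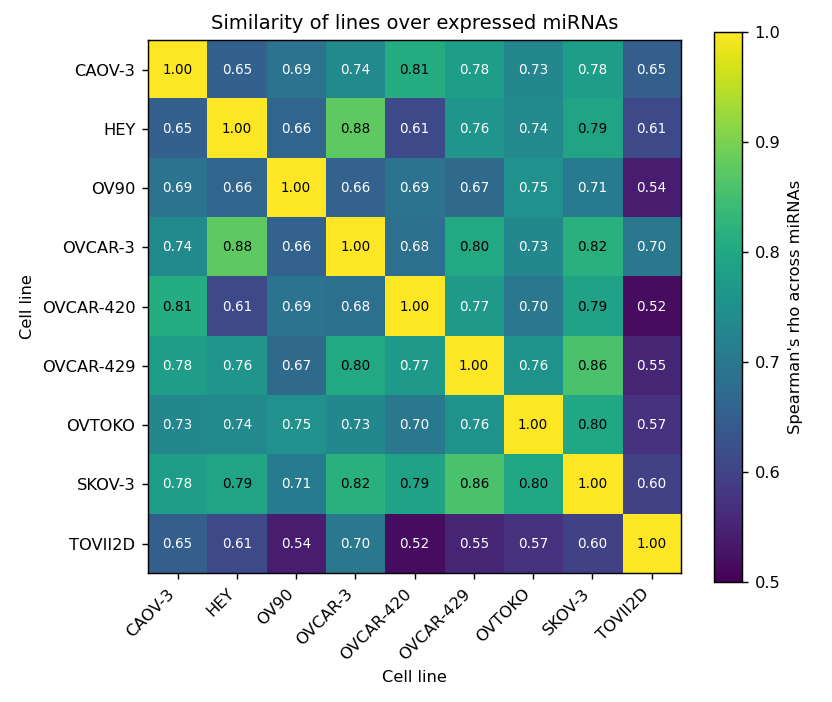
Heatmap of Spearman's rho across expressed miRNAs for each pair of the 9 cell lines (lines on both axes, rho on the colour scale, 1 library per line). HEY and OVCAR-3 stand highest at 0.876, and OVCAR-420 and TOVII2D lowest at 0.517.

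The second comparison was which miRNAs differed most over the lines. The widest spread belonged to miR-31-5p, encoded beside the CDKN2A locus in chromosome band 9p21 (hairpin on chromosome 9, 21512115 to 21512185 in GRCh38). It stood at 10213 normalized CPM in SKOV-3, 8009 in OVTOKO and 5611 in OVCAR-420. The same miRNA had 7 reads in HEY, 6 in TOVII2D and 0 in OVCAR-3, and its SD on the log2 scale was 5.36. Next was miR-205-5p, an epithelial miRNA typical of squamous and basal cells, from an exon of MIR205HG on chromosome 1. It reached 38989 normalized CPM in OVCAR-420 and 13314 in OVCAR-429, against 7.57 in OVTOKO and 8.15 in OVCAR-3 (SD 4.96). The lymphoid and inflammatory miR-155-5p, from an exon of MIR155HG on chromosome 21, ran from 1343 in HEY and 841 in OVCAR-429 to 0 in TOVII2D (SD 4.13).

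Epithelial, mesenchymal and imprinted miRNAs made up the rest of the 10 widest. The epithelial miR-200b-3p ran from 5948 normalized CPM in OVCAR-420 to 0.679 in TOVII2D (SD 4.31), and miR-429 of the same cluster from 681 in OVCAR-420 to 0 in OV90 and TOVII2D (SD 3.99). The mesenchymal miR-199a-5p stood at 5072 in TOVII2D and at 65.2 or less in every other line (SD 4.17). Its partner arms miR-199a-3p and miR-199b-3p, which share their sequence, had SDs of 4.07 and 4.07. The imprinted miR-381-3p stood at 1599 in TOVII2D and 510 in CAOV-3 but 0 in HEY, OV90, OVCAR-429 and SKOV-3 (SD 4.15). The imprinted miR-654-3p had 1612 and 410 in the same lines (SD 4.11). Of the 395 expressed miRNAs, 188 (47.6%) ranged over at least 4 on the log2 scale between the lowest and the highest line. The median range was 3.60 and the median SD 1.20, and 0 miRNAs ranged under 1. These are spreads between lines, which hold biological and technical differences together. With a mean of at least 100 normalized CPM required, 82 miRNAs met the rule.

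**Figure D2:**
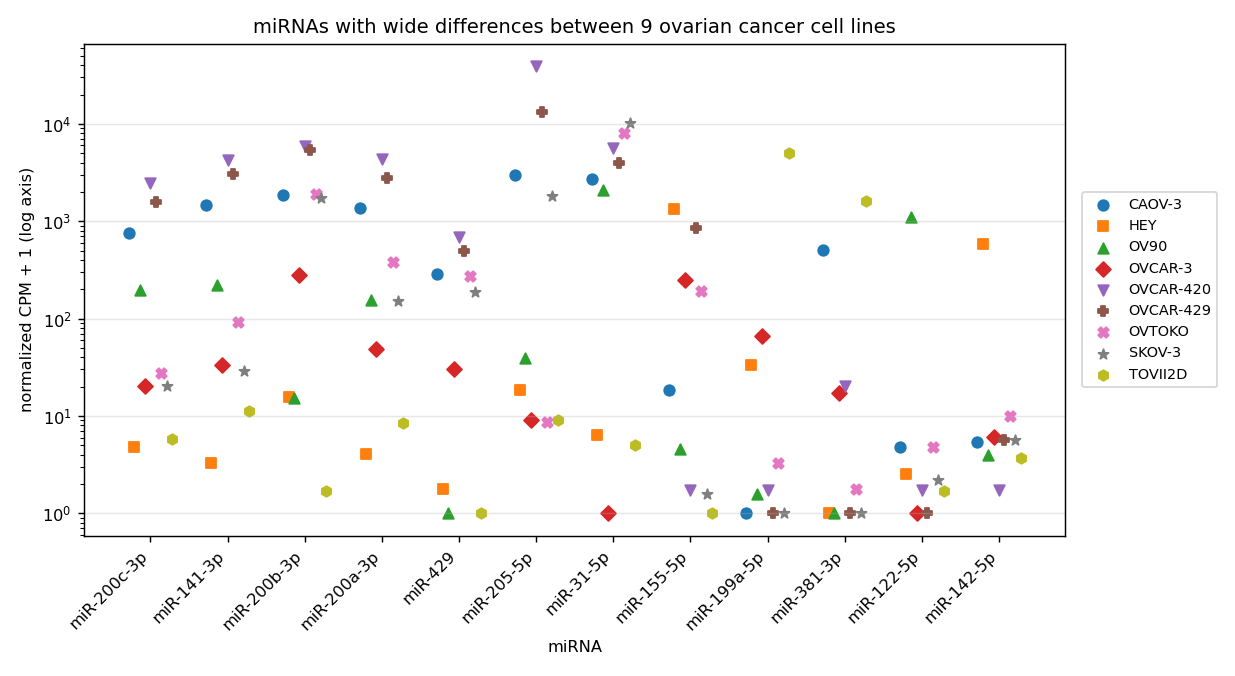
Normalized CPM plus 1 (vertical, log axis) of 12 miRNAs (horizontal) in each of the 9 cell lines, with 1 marker per library. The miR-31-5p level runs from 0 in OVCAR-3 to 10213 in SKOV-3, and miR-122-5p stands at 1110 in OV90 and at 3.85 or less elsewhere.

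The third comparison was which miRNAs were high in a single line. The liver miRNA miR-122-5p, from an exon of MIR122HG on chromosome 18, stood at 1110 normalized CPM in OV90. That was 288-fold above the next line, CAOV-3 (interval 140 to 718). OV90 also held miR-483-3p and miR-483-5p, processed from an intron of the growth factor gene IGF2 on chromosome 11. The miR-483-3p level was 555, against 1 read in the next line (ratio 590, interval 105.6 to 23329), or 181.7-fold against the floor. The other arm, miR-483-5p, with 430 reads in OV90 and 0 in all other lines, was at least 83.7-fold higher. The haematopoietic miRNA miR-142-5p, on chromosome 17, stood at 578 in HEY, 63.6-fold above OVTOKO (36.2 to 123.6). Its opposite arm miR-142-3p stood at 125.9 in HEY, a ratio of 83.1 (22.6 to 692) to OVTOKO with 2 reads, or 41.2-fold against the floor.

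Other blood cell markers in HEY stood at different levels. The red cell miR-486-5p stood at 1916 normalized CPM, the lymphoid miR-150-5p at 6.14 and the myeloid miR-223-3p at 0.768, which is 1 read. The blood cell marker list was 0.45 in HEY, at percentile 94.0 of random lists, with 4 of 5 members above the mean of the other lines. The third miRNA high in HEY was miR-3152-5p, at 43.0 normalized CPM, a ratio of 24.1 (7.83 to 120) to OV90 with 3 reads.

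OVCAR-420 held miR-184, known from corneal and lens epithelium, at 462 normalized CPM, 76.3-fold above OVTOKO (38.5 to 177). It also held miR-944, from an intron of the squamous transcription factor gene TP63 on chromosome 3, at 296, which was 45.7-fold above SKOV-3 (25.3 to 92.4). The third was miR-767-5p, from an intron of GABRA3 on the X chromosome, at 695 and 4.92-fold above CAOV-3 (4.28 to 5.67). OVCAR-429 held miR-504-5p, from an intron of FGF13 on the X chromosome, at 226, 55.4-fold above OVCAR-3 (21.4 to 205.1). OVCAR-3 held miR-34c-5p, a miRNA induced by p53, at 427, 4.49-fold above CAOV-3 (3.75 to 5.39).

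TOVII2D held miR-214-3p, from the DNM3OS transcript on chromosome 1, at 678 normalized CPM and 111-fold above OVCAR-3 (50.8 to 303). In the same line miR-199a-5p, which has a hairpin in DNM3OS and another on chromosome 19 that its reads do not tell apart, was 77.8-fold above OVCAR-3 (60.8 to 101). The level of miR-599 in TOVII2D was 223.3, a ratio of 295 (52.6 to 11681) to OVTOKO with 1 read, or 73.1-fold against the floor. CAOV-3 held both arms of miR-1247, from an exon of DIO3OS in the imprinted region of chromosome 14. Its 5p arm stood at 35.7, a ratio of 35.1 (6.08 to 1406) to OVCAR-3 with 1 read, or 11.7-fold against the floor. Its 3p arm was at least 9.53-fold higher than in the lines with 0 reads. In CAOV-3, miR-20b-5p was 6.01-fold above OVCAR-429 (3.14 to 12.9). OVTOKO held miR-489-3p and miR-653-5p, neighbours in an intron of the calcitonin receptor gene CALCR on chromosome 7. They stood 8.34-fold (5.19 to 14.1) and 6.78-fold (4.88 to 9.63) above OV90. The miR-486-3p level in OVTOKO was 5.98-fold above CAOV-3 (5.13 to 6.99), and 3.96-fold with the library total as the only scaling, which is below the rule.

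In all, 63 miRNAs stood at least 4-fold above every other line with at least 50 reads. TOVII2D held 28 of them, of which 11 came from the imprinted chromosome 14 cluster, OV90 11, CAOV-3 7, OVTOKO 6, HEY 5, OVCAR-420 4, OVCAR-3 1, OVCAR-429 1 and SKOV-3 0. The count was 38 where 200 reads were required. Without TOVII2D, 56 met the rule, 35 of them among the 63. With 1 miRNA per near-identical group 53 met it, 6 of them in OV90 and 4 in CAOV-3, where 5 of the 11 in OV90 had been near-identical miR-548 arms.

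Lower levels in a single line met the mirrored rule for 14 miRNAs. Among them was miR-130a-3p, known from vascular and blood cells, with 3 reads in OVCAR-420, a ratio of 39.9 (13.3 to 196.4) below the next line, OVTOKO. The miR-224-5p level in TOVII2D was 1 read, a ratio of 77.0 (13.4 to 3085) below OVTOKO, or 25.7-fold with the floor. The endothelial miR-126-5p stood at 18.3 normalized CPM in OVCAR-3, 16.1-fold below OVTOKO (10.03 to 27.4). The immune-associated miR-181a-5p stood at 3833 in CAOV-3, 4.89-fold below OVCAR-429 (4.76 to 5.02). HEY was low in miR-501-3p (4.31-fold, 2.82 to 6.82) and OV90 in miR-4454 (4.44-fold, 3.67 to 5.41). OVCAR-420 held 5 of the 14, OV90 3, CAOV-3 2, HEY 2, OVCAR-3 1 and TOVII2D 1. The count moved to 9 with DESeq2 size factors, of which 8 were among the 14, and to 9 with the library total alone, of which 7 were. It was 35, the 14 included, where at least 10 reads were required, and 9, all among the 14, with 1 miRNA per near-identical group.

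Fixed lists of related miRNAs were then compared between lines. For each list the value is the median over members of the line minus the mean of the other 8 lines, in log2 of normalized CPM plus 1, and its percentile is among 10000 random lists of the same size and level. These values depend on scaling, as do the levels of single miRNAs given in normalized CPM above and below. With the library total alone the median miRNA moved by -1.002 in SKOV-3, -0.47 in OVTOKO, 0.52 in OVCAR-420, 0.43 in TOVII2D and 0.36 in OVCAR-429, and with DESeq2 size factors by between -0.29 in OVTOKO and 0.21 in OVCAR-420. List differences are read relative to these shifts, and directions below kept their sign under both scalings except where stated. The values given are mostly the highest and lowest line of a list, and some were ordinary for random lists. For example, the percentile was 18.6 for miR-106b/25 in HEY and 19.05 for miR-15/16 in TOVII2D. In OVCAR-420 it was 18.8 for miR-17/92 and 39.4 for miR-130/miR-301. Near-identical members count separately in the member counts below, so these counts can exceed the number of separate measurements.

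The miR-200 family, which represses ZEB1 and ZEB2 and holds cells in an epithelial state, divided the lines. Its median was 5.14 in OVCAR-420, 4.66 in OVCAR-429 and 3.26 in CAOV-3, each at the 100th percentile with 5 of 5 members more than 2-fold higher. It was -5.06 in HEY and -5.01 in TOVII2D, with 5 of 5 members more than 2-fold lower, and -2.16 in OVCAR-3. In OVCAR-420, miR-200c-3p stood at 2462 normalized CPM, miR-141-3p at 4260, miR-200a-3p at 4402 and miR-429 at 681. In HEY these were 3.84, 2.30, 3.07 and 0.768. SKOV-3 and OVTOKO were split between the 2 loci of the family. In SKOV-3 the chromosome 1 members miR-200b-3p and miR-200a-3p stood at 1723 and 151.6 while the chromosome 12 members miR-200c-3p and miR-141-3p stood at 19.4 and 28.2. In OVTOKO miR-200b-3p stood at 1895, miR-200a-3p at 381.8, miR-200c-3p at 26.5 and miR-141-3p at 90.1. In OV90 the levels were mixed, with miR-200c-3p at 197, miR-141-3p at 220.1 and miR-200a-3p at 153, but miR-200b-3p at 14.3 and miR-429 at 0. The 3p arms of miR-200b and miR-200c, and of miR-200a and miR-141, differ at 1 base each, so their separate values are uncertain where reads could be counted at both. For miR-200b-3p and miR-200c-3p the log2 ratio had an SD of 3.41 over the lines. Full sharing of reads would keep that ratio steady, so the values argue against it for this pair. The lower value of the pair in a line stays uncertain.

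Lists of mesenchymal and stromal miRNAs followed other lines. The miR-199/miR-214 list was highest in TOVII2D, at 9.86, and lowest in OVCAR-420, at -5.55, with 3 of 3 members in each direction. OVCAR-3 stood at 2.95, with 3 of 3 members more than 2-fold higher. HEY stood at 2.45, a value set by miR-199a-3p and miR-199b-3p, which share their sequence and count as 1 measurement, while miR-214-3p had 0 reads there. The counts of 3 members in the other lines hold the same pair. The miR-143/miR-145 list, abundant in smooth muscle, stood at 4.81 in CAOV-3 and 4.70 in OV90. There miR-143-3p reached 2381 and 1931 normalized CPM, against 35.6 or less in the other 7 lines, and miR-145-5p had 20 reads in each of these 2 lines and 0 in the others. The lowest miR-143/miR-145 value was -2.05, in OVCAR-3. The miR-29 family, which represses collagen genes, was highest in HEY, at 1.15, and lowest in OVTOKO, at -1.34, with miR-29a-3p at 4594 and 915. In the same lines miR-29b-3p stood at 180 and 75.7. For miR-221/miR-222, which repress the cell cycle inhibitor CDKN1B, the median was 1.46 in HEY and -1.26 in OV90. The miR-221-3p level ran from 846 in TOVII2D to 5458 in HEY, and that of miR-222-3p from 2169 in OV90 to 16700 in OVCAR-429.

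The imprinted, placental and embryonic clusters were each high in few lines. Member counts cover only members with a mean of at least 1 normalized CPM, 40 of 49 fixed for 14q32 and 10 of 37 for C19MC. A member can reach that mean through the lines where it is high, so these counts do not describe the whole clusters. The chromosome 14q32 cluster of the DLK1-DIO3 imprinted region was highest in TOVII2D, at 4.88, with 40 of 40 members more than 2-fold higher, and next in CAOV-3, at 3.17, with 39 of 40. It was lowest in OV90 and OVCAR-429, at -1.38 in both, with 34 and 33 of 40 members more than 2-fold lower. Its most abundant member, miR-411-5p, stood at 1897 normalized CPM in TOVII2D, 536 in CAOV-3 and 0 in OV90. The primate-specific C19MC cluster of chromosome 19, active in placenta, stood at 4.11 in OVCAR-429, with 10 of 10 members more than 2-fold higher, and at 2.76 in SKOV-3. It stood at 1.36 in CAOV-3 and at -1.37, the lowest value, in HEY, OV90, OVCAR-3, OVTOKO and TOVII2D alike. Its member miR-1283 had 131 reads in OVCAR-429, 99 in SKOV-3 and 19 in CAOV-3. The embryonic stem cell list miR-371/miR-373 was 3.80 in OVCAR-429, where miR-371a-5p had 29 reads, and -0.79 in CAOV-3 and 5 other lines. The embryonic list miR-302/miR-367 was 3.05 in CAOV-3, where miR-302a-3p and miR-302d-3p stood at 9.34 each, 1.41 in OV90 and -0.68 in HEY and 5 other lines. Members of both embryonic lists lay near the floor in most lines, and with a pseudocount of 5 the same values were 2.05 in OVCAR-429 and 1.40 in CAOV-3, the second of which was 4.65 with a pseudocount of 0.25. With a pseudocount of 5 the 14q32 value in TOVII2D was 3.03 and that of C19MC in OVCAR-429 was 2.40. Of the 17 miRNAs fixed for the Xq27.3 testis-associated cluster, 1 was measured, miR-891a-5p, with 40 reads in HEY, 11 in SKOV-3 and 5 or fewer elsewhere.

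Lists tied to position in the body axis and to cell cycle control also separated single lines. HOX cluster miRNAs were lowest in OVCAR-420, at -4.08, with 5 of 5 members more than 2-fold lower. There miR-10a-5p stood at 3579 normalized CPM, against 274402 in SKOV-3. The 5 members include miR-10a-5p with miR-10b-5p and miR-196a-5p with miR-196b-5p, which are near-identical pairs. They are fewer than 5 separate measurements where reads were counted at both arms. The HOX list was highest in OV90, at 2.01, with TOVII2D at 1.98, and miR-615-3p ran from 511 in CAOV-3 to 2.35 in SKOV-3. The miR-424/miR-503 cluster, which restrains cyclins, was -5.30 in OVCAR-420, or -3.13 with a pseudocount of 5, with 5 of 5 members more than 2-fold lower and 0 reads of miR-424-3p, and 1.73 in OVTOKO. For miR-224/miR-452, within the GABRE gene on the X chromosome, the value was 4.07 in OVCAR-420, where miR-224-5p stood at 1780, and -6.41 in TOVII2D. The miR-15/16 family, which represses BCL2 and cyclins, was 1.72 in OVCAR-3, where miR-16-5p stood at 29006, and -0.64 in TOVII2D. Its member miR-497-5p was highest in TOVII2D, at 119. The p53-responsive miR-34/miR-449 list was 2.09 in CAOV-3, or 0.89 with a pseudocount of 5, and -1.53 in OVTOKO, although miR-34a-5p was highest in OVTOKO, at 614, and had 0 reads in SKOV-3, 7 in TOVII2D and 8 in OVCAR-3.

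The MYC-induced miR-17/92 cluster was 1.04 in HEY, with 3 of 6 members more than 2-fold higher, and -1.10 in OVCAR-420, with 4 of 6 lower. The miR-92a-3p level, whose reads also match a hairpin on the X chromosome, ran from 22374 normalized CPM in SKOV-3 to 62655 in HEY, and miR-19a-3p from 203.2 in OVCAR-420 to 1212 in HEY. The related miR-106b/25 cluster, within MCM7, was -1.49 in HEY and 0.94 in OV90, with miR-93-5p at 518.1 and 3276 and miR-25-3p at 1540 and 4305. The third paralogous cluster, miR-106a/miR-363, was 1.88 in CAOV-3, where miR-363-3p stood at 398, and -1.16 in SKOV-3. Its most abundant member, miR-106a-5p, ran from 227 in SKOV-3 to 667 in HEY. The let-7 family, which represses HMGA2 and RAS genes, was -1.07 in TOVII2D, with 5 of 9 members more than 2-fold lower, and 0.61 in OVCAR-3. Within it let-7b-5p ran from 211 in OV90 to 4611 in CAOV-3, while let-7a-5p ranged only from 40455 in TOVII2D to 82727 in OVCAR-3. By share of reads let-7a-5p was lowest in OVTOKO, at 3.26%, and highest in OVCAR-420, at 8.63%.

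The list of miR-99, miR-100 and miR-125, partly clustered with let-7 genes, was 3.65 in HEY and -4.97 in OV90. The miR-100-5p level was 16051 normalized CPM in HEY, 24.4 in OV90 and 41.7 in OVTOKO. The opposite order held for miR-125a-5p, with 2851 in HEY and 13697 in OV90. The miR-30 family was 2.40 in SKOV-3, 2.18 in OVTOKO and -2.21 in OV90, and miR-30d-5p ran from 4969 in OV90 to 189834 in SKOV-3. By share of reads miR-30d-5p was highest in OVTOKO, at 10.8%. The miR-181 family was -2.39 in CAOV-3, with 3 of 4 members more than 2-fold lower, and 0.69 in OVCAR-3, while miR-181c-5p was highest in TOVII2D, at 1133. Its members miR-181b-5p and miR-181d-5p are near-identical. The miR-183/miR-96/miR-182 cluster, known from sensory organs and epithelia, was -2.30 in HEY, with 3 of 3 members more than 2-fold lower, and 0.96 in OVCAR-420. There miR-182-5p stood at 2524 and 18822. The miR-23/27/24 list was 1.51 in OVCAR-3, with 5 of 5 members more than 2-fold higher, and -1.15 in OV90. Its 5 members include the near-identical pairs miR-23a-3p with miR-23b-3p and miR-27a-3p with miR-27b-3p. The level of miR-27b-3p was 52597 in OVCAR-3 and that of miR-23a-3p 2475. The miR-130/miR-301 family was 1.45 in OV90 and -0.58 in OVCAR-420, the second of which was 0.00 with the library total alone.

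Markers of other tissues were measured to describe which of them the lines held. The list of other organ markers was 6.63 in OV90, with 3 of 3 members more than 2-fold higher, and -3.11 in OVCAR-3. In OV90 the islet and neuroendocrine miR-375 stood at 2871 normalized CPM and the endothelial miR-126-5p at 1874, beside the liver miR-122-5p. Blood cell markers were 0.65 in CAOV-3 and -1.49 in OVCAR-420, the second of which was -2.99 and -0.47 with pseudocounts of 0.25 and 5. The red cell miRNA miR-486-5p has a hairpin in an intron of ANK1 and another on the opposite strand. It stood at 88289 in OVTOKO and 21779 in CAOV-3, and between 121 and 1916 in the other lines. Muscle markers, with 2 of 7 members measured, were 1.12 in TOVII2D and -0.61 in OVCAR-420. In TOVII2D miR-133a-3p, with 20 reads, was more than 2-fold higher and the other member more than 2-fold lower. Neural markers were 2.75 in TOVII2D and -2.09 in both OV90 and OVTOKO, with miR-137 highest in SKOV-3, at 62.3. With a pseudocount of 5 the muscle and neural values in TOVII2D were 0.71 and 1.59. The hypoxia-induced miR-210-3p, the only member of its list, stood at 1752 in OVTOKO, 924 in SKOV-3, 584 in CAOV-3, 414 in HEY, 280 in OVCAR-3, 161 in OVCAR-420, 121 in TOVII2D, 48.8 in OV90 and 44.3 in OVCAR-429, with all lines at the same oxygen level.

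The list of squamous and oncogenic single miRNAs was 3.69 in OVCAR-429 and -2.57 in HEY, with 4 of 7 members more than 2-fold lower and 3 more than 2-fold higher in HEY. Its member miR-21-5p ran from 39939 normalized CPM in TOVII2D to 248989 in SKOV-3, while by share of reads it was highest in HEY, at 18.5%. The list of miRNAs that earlier literature ties to platinum response, of which 15 of 18 were measured, was 0.50 in OV90 and -1.49 in HEY. In HEY 9 of the 15 were more than 2-fold lower and 3 more than 2-fold higher. Between scalings the line at an extreme changed for several lists. With the library total alone the highest line became OVCAR-420 for let-7 (0.72), OVCAR-429 for miR-221/miR-222 (1.73) and miR-29 (1.37), OVTOKO for miR-30 (1.64) and TOVII2D for miR-424/miR-503 (1.30). Under that scaling SKOV-3 was lowest for miR-17/92 (-1.87), let-7 (-0.66), miR-15/16 (-1.06), miR-221/miR-222 (-1.37), miR-143/miR-145 (-2.33) and miR-130/miR-301 (-0.90). It also gave -0.50 for miR-17/92 in OVCAR-420, -0.58 for let-7 in TOVII2D and 1.24 for miR-30 in SKOV-3. With either alternative the highest line became TOVII2D for the HOX list (2.14 with DESeq2 size factors) and OVCAR-420 for miR-181 (0.75), and with DESeq2 size factors it became OV90 for miR-143/miR-145 (4.78). With DESeq2 size factors the lowest line became CAOV-3 for miR-15/16 (-0.67) and HEY for miR-130/miR-301 (-0.36).

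**Figure D3:**
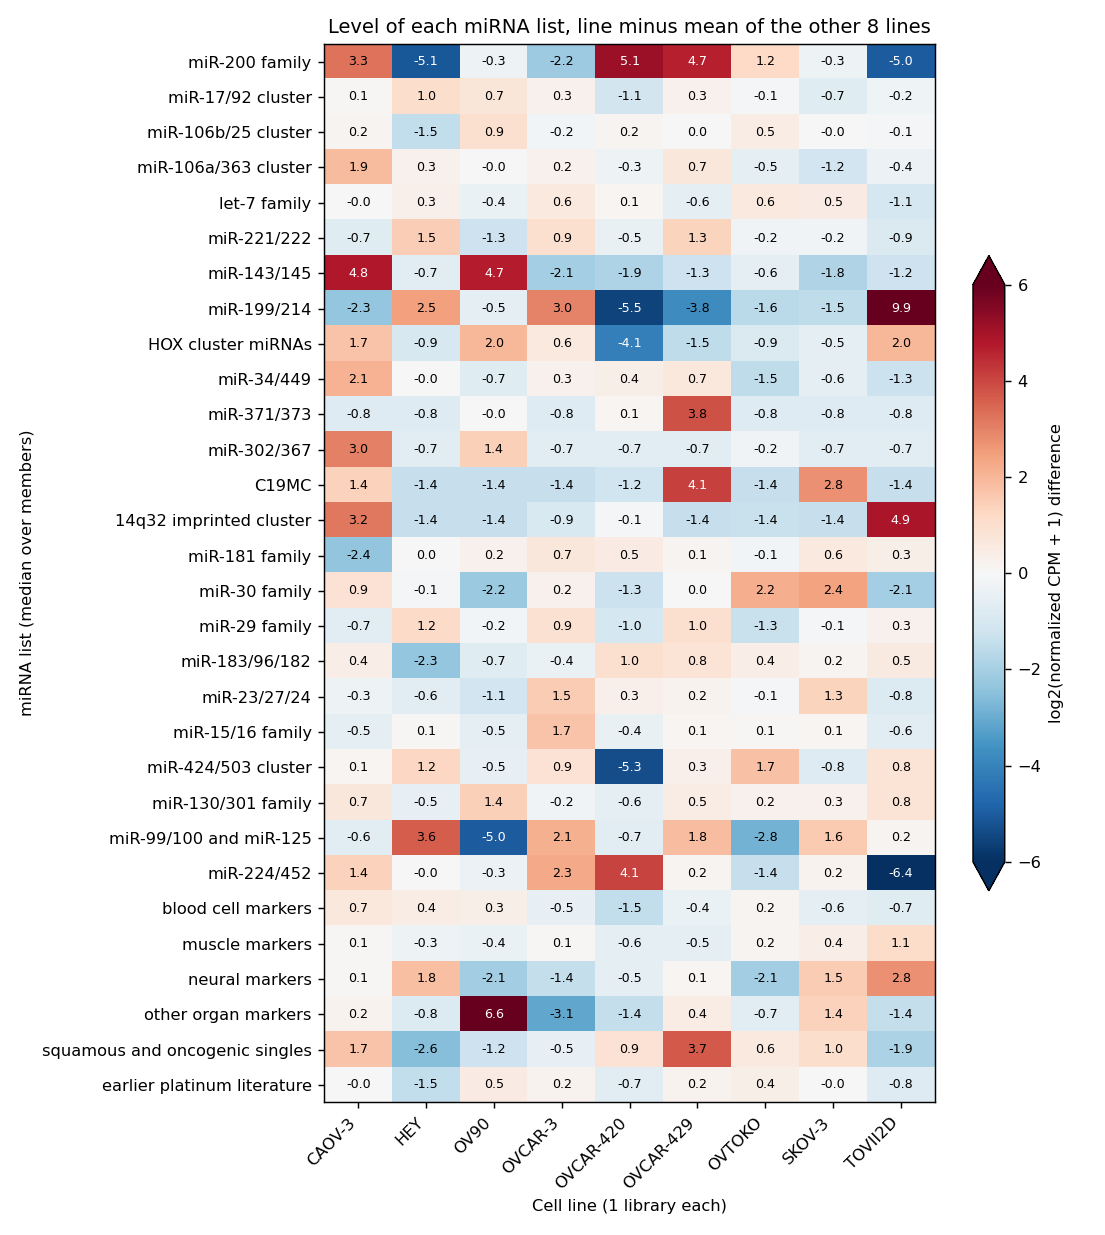
Heatmap of the median difference between each of the 9 cell lines (horizontal, 1 library each) and the mean of the other 8, in log2 of normalized CPM plus 1 (colour and printed values), for 30 miRNA lists (vertical). The miR-200 family runs from 5.14 in OVCAR-420 to -5.06 in HEY and miR-199/miR-214 reaches 9.86 in TOVII2D, and values near 0 change sign between scalings in some lines.

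The next comparison tested whether members of a list varied together over the 9 lines. The closest lists were miR-224/miR-452, with a mean pairwise r of 0.988, C19MC, with 0.962 over 3 members, and the 14q32 cluster, with 0.948 over 16 members. Next came miR-199/miR-214 with 0.919, miR-424/miR-503 with 0.913, miR-183/miR-96/miR-182 with 0.908, miR-30 with 0.878 and miR-200 with 0.820. Each had an adjusted p of 2.273e-04 from a permutation p of 1e-04, the smallest that 10000 shuffles can give (one-sided permutation test, n = 9 lines, Benjamini-Hochberg over 25 lists). The miR-23/27/24 list (0.797), the miR-17/92 cluster (0.729) and the HOX list (0.620) had the same adjusted p. Also passing were miR-106b/25 with 0.855 and miR-29 with 0.820, at an adjusted p of 3.846e-04 each by the permutation test. Lower values passed for miR-221/miR-222 (0.792, permutation adjusted p = 0.0113), other organ markers (0.537, 0.00234), miR-181 (0.421, 0.0149), miR-15/16 (0.416, 0.00234), miR-130/miR-301 (0.297, 0.0180) and let-7 (0.279, 7.143e-04).

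In all, 19 of the 25 lists passed and 6 did not. Those 6 were miR-106a/miR-363 (mean r 0.226, permutation adjusted p = 0.0983), miR-99/miR-100 and miR-125 (0.153, 0.123), blood cell markers (0.264, 0.236), squamous and oncogenic singles (0.0167, 0.407), earlier platinum literature (-0.0230, 0.718) and miR-34/miR-449 (-0.0577, 0.581). Random lists of the same level had median values close to 0, from -0.0390 to 0.0229. Some lists hold near-identical members whose reads can be counted at both, so that 1 measurement can count as 2 members. With 1 miRNA per near-identical group, 16 of 23 lists passed, and miR-181 (0.214, permutation adjusted p = 0.175) and miR-130/miR-301 (0.182, 0.152) no longer did. Among lists that still passed, mean r fell for miR-199/miR-214 (0.879, permutation adjusted p = 0.0110), the HOX list (0.524, 0.0141) and C19MC (0.934, 9.200e-04). It also fell for miR-17/92 (0.692), miR-30 (0.816) and miR-23/27/24 (0.772), and rose for miR-200 (0.889), let-7 (0.769) and miR-15/16 (0.544). The miR-29 family, which passed above, and miR-106a/miR-363 kept fewer than 2 members and could not be tested, so the miR-29 result rests on arms whose reads can be counted at each other. The pass was lost for miR-15/16 without OVCAR-3 (0.0120), for let-7 without TOVII2D (0.120) and for other organ markers without OV90 (0.419). The miR-130/miR-301 result was lost without OV90 (0.0828) and without OVCAR-420 (0.230). Passes were gained by miR-99/miR-100 and miR-125 without OV90 (0.445, permutation adjusted p = 0.00268) and without HEY (0.235, 0.0451), and by miR-106a/miR-363 with the library total alone (0.468, 0.00528).

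Of 12 miRNA pairs fixed in advance, 11 could be tested over the 9 lines and 6 passed. The neighbours miR-200c-3p and miR-141-3p on chromosome 12 (hairpins at 6963699 to 6963766 and 6964097 to 6964191 in GRCh38) had a Pearson r of 0.986. The two-sided exact permutation p was 5.511e-06 (adjusted 6.063e-05 over 11 pairs, n = 9), and Spearman's rho was 0.983 (exact p = 4.960e-05, adjusted 5.456e-04). Without OVCAR-420 and OVCAR-429, the 2 lines farthest from the median, r was 0.970. For miR-183-5p and miR-182-5p r was 0.957 (exact permutation p = 1.378e-04, adjusted 7.578e-04), rho 0.917 (p = 0.00131, adjusted 0.00721), and r without HEY and OVCAR-420 was 0.786. For miR-100-5p and miR-125b-5p, both with a hairpin in introns of MIR100HG on chromosome 11, r was 0.902 (exact permutation p = 3.858e-04, adjusted 0.00141), rho 0.850 (p = 0.00607, adjusted 0.0181), and r without OV90 and OVTOKO 0.792. With the library total alone the lines split into clusters, and r within 7 lines was 0.767, which did not pass (exact permutation adjusted p = 0.0810). The values are not those of 1 locus alone, since miR-125b-5p has a second hairpin in MIR99AHG on chromosome 21 and miR-100-5p differs at 1 base from miR-99a-5p, with a steady ratio over the lines (SD 0.0838 on the log2 scale).

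For miR-17-5p and miR-20a-5p, from exons of MIR17HG, r was 0.857 (exact permutation p = 0.00343, adjusted 0.00942), rho 0.817 (p = 0.0108, adjusted 0.0237), and r without OVCAR-420 and SKOV-3 was 0.797. A stretch of 20 bases in these arms differs at 1 base, so the pair is not independent where reads were counted at both. For miR-200a-3p and miR-429 r was 0.834 (exact permutation p = 0.00779, adjusted 0.0171), rho 0.845 (p = 0.00657, adjusted 0.0181), and r without HEY and OVCAR-420 was 0.763. For miR-221-3p and miR-222-3p r was 0.792 (exact permutation p = 0.0118, adjusted 0.0215) and r without HEY and TOVII2D was 0.938. The pass was lost without HEY alone (0.731, exact permutation adjusted p = 0.06998) and without OVCAR-429 alone (0.759, 0.0526). Its rho of 0.717 did not pass after adjustment (p = 0.0369, adjusted 0.0579).

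The family members miR-200c-3p and miR-200b-3p, on different chromosomes, gave an r of 0.660 (exact permutation p = 0.0571, adjusted 0.0785), which did not pass. Their rho of 0.767 did (p = 0.0214, adjusted 0.0392), and r without OVCAR-420 and OVCAR-429 was 0.444. The epithelial pair miR-200c-3p and miR-183-5p had an r of 0.624 (exact permutation p = 0.0561, adjusted 0.0785), a rho of 0.617 (p = 0.0857, adjusted 0.118) and, without the same 2 lines, an r of 0.412. Leaving out TOVII2D alone gave 0.833, which passed (adjusted p = 0.00698). For miR-10a-5p and miR-196a-5p r was 0.549 (exact permutation p = 0.132, adjusted 0.161), rho 0.533 (p = 0.148, adjusted 0.180), and r without OVCAR-420 and OVCAR-429 was -0.0340, so the relation rested on those lines. For let-7b-5p and miR-125b-5p r was 0.390 (exact permutation p = 0.291, adjusted 0.320), rho 0.333 (p = 0.385, adjusted 0.424) and r without OV90 and OVCAR-429 0.163. The epithelial miR-200c-3p and miR-221-3p had an r of -0.0773 (exact permutation p = 0.839, adjusted 0.839), a rho of -0.200 (p = 0.613, adjusted 0.613) and, without OVCAR-420 and OVCAR-429, an r of -0.299. The pair of miR-143-3p and miR-145-5p was not tested, since miR-145-5p had a mean of 2.54 normalized CPM. No sequencing batch is given in the labels, so no relation was recomputed within batches.

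The last comparison was which arm of a hairpin was more abundant, a ratio within each library that no scaling changes. Of 105 hairpin stems with at least 20 reads in every line, 3 changed their more abundant arm between lines with 95% Wilson intervals on both sides of an equal share. For miR-548o the 5p share was 92.2% (88.9 to 94.6) in OV90 and 11.4% (6.79 to 18.5) in SKOV-3. For miR-106b it was 77.7% (73.2 to 81.5) in TOVII2D and 37.2% (34.3 to 40.1) in OVTOKO. For miR-361 it was 72.0% (67.4 to 76.2) in OV90 and 41.0% (37.6 to 44.5) in CAOV-3. The last 2 stems fell outside the naming rule and were named after their values were seen.

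The median range of the log2 ratio of 5p over 3p reads was 2.56. The widest belonged to let-7c, at 9.19, with 91 reads of let-7c-3p in TOVII2D and 3 or fewer in every other line. It was followed by miR-99a, at 8.22, whose 5p share was 91.4% (90.2 to 92.4) in TOVII2D and 99.97% (99.92 to 99.99) in SKOV-3. The ranges of miR-548o, miR-27a and miR-33b were 6.45, 5.78 and 5.69. For let-7c, miR-99a and miR-33b the ratio rested on an arm with 3 or fewer reads in some lines, so its range depends on the value added to each count. The 5p arms of let-7c, miR-99a and miR-548o and the 3p arms of miR-27a and miR-548o have near-identical relatives elsewhere in the genome, so their shares are uncertain.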

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

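Dixon's test of single lines was planned, while both tests on near-identical arms, on both explanations for miR-486 and on mixing of libraries were chosen after the results they measure were seen, as was the redrawing of miRNAs.

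A single line stood far from the other 8 in 7 of 33 measures. Chance alone would give about 1.65 for independent, normally distributed measures. Some lists share members, and list values can tie at the floor, as most lines did at -0.79 for miR-371/miR-373. The excess over 1.65 is therefore not a test. With the library total as the only scaling, 4 of the 7 remained. For 6 of them the measure was a list median in log2. OV90 was high in other organ markers, at 6.63 against a median of -0.67 over the 9 lines. OVCAR-420 was low in the miR-424/miR-503 cluster, at -5.30 against 0.28. OVCAR-429 was high in miR-371/miR-373, at 3.80 against -0.79. CAOV-3 was low in the miR-181 family, at -2.39 against 0.24. OVCAR-3 was high in the miR-15/16 family, at 1.72 against 0.05. HEY was low in the miR-106b/25 cluster, at -1.49 against 0.04. Random lists of the same size and level often fell as low in HEY, where this value was at percentile 18.6. The last measure was the library total, 4068762 in SKOV-3 against a median of 1798001.

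The red cell miRNA miR-486-5p stood at 88289 normalized CPM in OVTOKO and 21779 in CAOV-3. RNA from red blood cells would bring miR-451a, their leading miRNA, which had 2 reads in OVTOKO and 5 in CAOV-3 and at most 0.0126% of the miR-486-5p level, so the tables argue against it. Reads of another RNA assigned to the 5p arm are argued against by miR-486-3p, which followed miR-486-5p over the 9 lines with r = 0.943 (exact permutation p = 1.102e-05) and rho = 0.95 (exact p = 3.527e-04), and r = 0.984 without CAOV-3 and OVTOKO. No biological explanation was tested, and a higher output of the MIR486 locus at ANK1 in these lines remains a hypothesis. The locus has a hairpin on each strand, which the reads do not tell apart.

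HEY and OVCAR-3 were the closest pair of lines, at a rho of 0.876, and no biological explanation was tested. Mixing of RNA or reads at a share of 10% or more would carry every abundant miRNA across, but 3 miRNAs of HEY and 2 of OVCAR-3 with at least 400 normalized CPM stayed below 5% in the other line, which missed the 3 in each direction that the test first required. The reading against mixing at that share therefore rests on the counting limits, with miR-142-5p in OVCAR-3 at 0.882% of its HEY level (upper limit 2.07%) and miR-146b-5p in HEY at 2.06% of its OVCAR-3 level (upper limit 2.42%). With 1 miRNA per near-identical group their rho was 0.858 and that of the next pair, OVCAR-429 and SKOV-3, 0.855, so the pair stayed closest, which had been set in advance as the outcome against shared reads. The lead of 0.00256 had a 95% range of -0.0479 to 0.0534 over 1000 redraws of the miRNAs, which were added after that outcome was seen, so the part of shared reads was changed from argued against to open.

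Pairs of near-identical arms often kept nearly the same ratio in every line, as miR-10a-5p with miR-10b-5p (SD 0.0424 on the log2 scale) and miR-29a-3p with miR-29c-3p (SD 0.0420). Reads counted separately at both arms would scatter at least by sampling, but 17 of all expressed near-identical pairs scattered less (one-sided test against 10000 random tables, Benjamini-Hochberg adjusted p under 0.05), among them miR-19a-3p with miR-19b-3p (adjusted p = 0.0117) and miR-199a-3p with miR-199b-3p (0.00124), so for these pairs the values fit the same reads being counted at both arms. Of the 26 pairs with an SD under 0.1, 16 were among the 17 and 10 were not. Those 10 include miR-10a-5p with miR-10b-5p and miR-29a-3p with miR-29c-3p, for which shared counting and joint regulation both stay open. Not passing does not speak against shared counting, since arms that share most but not all reads can scatter more than sampling. The mean log2 ratios of these named pairs were 0.0529 and 0.125, so their counts were also nearly equal, which joint regulation alone does not require. An earlier test compared the ratios with those of the opposite arms and found near-identical arms steadier in 7 of 12 pairs, with median SDs of 0.377 and 0.852 (exact one-sided sign test p = 0.387), but 8 of the 12 lacked the steady ratio and the 12 held neither named example, so it decides nothing. Its first form gave 1 of 5 pairs with an error in the pairing, its corrected form with the first minimum gave 1 of 2, and the 12 came from lowering that minimum afterwards.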

How the results depend on the processing

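The leave-one-out runs of line-high counts and similarity, the settings with every deposited entry or 1 miRNA per near-identical group, and the other scalings of the measures with a line standing apart were chosen after the results were seen.

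No paired analysis was possible because each line had 1 library. Of the line-high counts, 15 of 16 stayed within 1.5 times of 63, and the other was 38 with at least 200 reads. Line-low counts moved from 14 to 9 with DESeq2 size factors, 9 with the library total alone, 35 with at least 10 reads and 9 with 1 miRNA per near-identical group. The count of variable miRNAs moved from 188 to 82 with a mean of at least 100 and stayed within 1.5 times in 17 other settings. With no filter on low values the rho of the closest pair was 0.781 and that of OVCAR-420 and TOVII2D 0.636. OV90 and TOVII2D, at 0.597, then became the most distant pair. HEY and OVCAR-3 stayed the closest pair in all 16 settings run that held both, and OVCAR-420 and TOVII2D the most distant in the other 15 of 16. Spearman's rho uses ranks, so other pseudocounts could not change it. Other scalings and left-out lines acted only through the filter on mean level, so many of these runs could hardly change the order. Of 3 arm switches, 3 remained in thinned libraries and 2 with at least 100 reads. With the library total alone, miR-486-3p in OVTOKO was 3.96-fold above the next line, under the 4-fold rule.

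List medians were called moved at 1 SD between the 9 lines or more, which 8 did. With pseudocounts of 0.25 and 5, miR-371/miR-373 in OVCAR-429 was 5.34 and 2.05, miR-302/miR-367 in CAOV-3 4.65 and 1.40, and blood cell markers in OVCAR-420 -2.99 and -0.47. With a pseudocount of 5, miR-34/miR-449 in CAOV-3 was 0.89 and miR-424/miR-503 in OVCAR-420 -3.13. These lists hold members near 0, where the pseudocount sets the scale.

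Over all recalculations, co-variation lost its pass 7 times and gained it 3 times, and pairs lost it 3 times and gained it 1 time. With the library total alone, miR-106a/miR-363 passed (0.468), and miR-100 with miR-125b, whose lines then split into clusters, had r = 0.767 within 7 lines and did not pass (exact permutation adjusted p = 0.0810). With 1 miRNA per near-identical group, miR-181 (0.214) and miR-130/miR-301 (0.182) did not pass. Leaving out each line gave mean r from 0.120 (without TOVII2D) to 0.317 for let-7, 0.0120 (without OVCAR-3) to 0.677 for miR-15/16, and 0.0828 (without OV90) to 0.391 for miR-130/miR-301, which also did not pass without OVCAR-420 (0.230). The range was 0.0111 to 0.445 for miR-99/miR-100 and miR-125, which passed without OV90 or without HEY (0.235), and 0.419 (without OV90) to 0.623 for other organ markers. Values of r ran from 0.731 (without HEY) to 0.925 for miR-221 with miR-222, which also did not pass without OVCAR-429 (0.759), and from 0.510 to 0.833 (without TOVII2D, where it passed) for miR-200c with miR-183. The cause of these changes was not tested. Of the 7 measures with a line standing apart, 7 remained with DESeq2 size factors and 4 with the library total alone. Both counts include the library total of SKOV-3, which no scaling can change. Depth limits levels under 3 reads, which lay between 1.65 and 3.06 normalized CPM.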

Other observations

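The miRNAs in the next paragraphs, outside the planned lists, and the neighbour examples were chosen after their values were seen, as was the test of neighbours without near-identical arms, while the tests on miR-491 and on all neighbouring hairpins were set before their results.

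Several miRNAs outside the fixed lists differed widely between lines. The inflammation-associated miR-146a-5p and miR-146b-5p have a stretch of 20 bases that differs at 1 base but were high in different lines. Their log2 ratio had the widest SD (4.85) of all expressed near-identical pairs, so shared reads do not make the high values uncertain. The miR-146b-5p level was 6043 normalized CPM in OVCAR-429, 5731 in OVCAR-3 and 3146 in SKOV-3, where miR-146a-5p stood at 25.4, 80.5 and 16.5. In OV90 and OVTOKO miR-146a-5p stood at 1668 and 1019, against 545 and 31.8 for miR-146b-5p. The miR-708-3p level was 434 in HEY and 342 in OVCAR-3, and 4.70 or less in the other 7 lines, and miR-708-5p followed with 225 and 207. The level of miR-193a-3p ran from 1.47 in OVCAR-420 to 1355 in OVTOKO.

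Epithelial miRNAs of gut and kidney were uneven too. The miR-192-5p level was 18025 normalized CPM in OVCAR-420, 8727 in OVTOKO and 7527 in CAOV-3, against 649.6 in OVCAR-429 and 656.2 in HEY. Its near-identical relative miR-215-5p, whose values in other lines are uncertain beside it, stood highest in OV90, at 5176, and miR-194-5p, a cluster partner of both, was highest in OVCAR-420, at 602. TOVII2D held the activity-regulated pair miR-132-3p and miR-212-3p at 996 and 117, against 76.4 or less and 3.84 or less in the other lines. In OVCAR-420 miR-577 stood at 633, while OVCAR-429 and TOVII2D had 0 reads of it.

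Neighbouring hairpins may vary together because they share a transcript or chromatin domain. Over 85 pairs of hairpins within 10 kb, leaving out pairs near-identical to each other, the median r over the lines was 0.890. The highest median among 10000 random sets of pairs on different chromosomes was 0.208. Many of the 85 pairs share a hairpin and 23 lie on chromosome 14, while the random pairs were drawn singly. The random medians therefore spread too little to serve as a test, here and for the smaller set of pairs below. Without chromosome 14 the median over 62 pairs was 0.836. The r was below 0 in 7 pairs, lowest for miR-99b-5p with let-7e-5p at -0.423 (174 bp apart on chromosome 19) and miR-18b-5p with miR-363-3p at -0.358 (663 bp apart on the X chromosome). All 7 hold an arm with a near-identical relative elsewhere, so their r does not speak for the locus alone. With every such arm left out, 43 pairs on 7 chromosomes had a median r of 0.953, against at most 0.30 over 10000 random sets of such pairs on different chromosomes. The lowest r was 0.476, so 0 of the 43 were below 0. Of these, 21 lay outside chromosome 14, with a median of 0.903.

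The near absence of miR-31-5p in HEY, OVCAR-3 and TOVII2D could reflect loss of a 9p21 segment that reaches both MIR31 and MIR491, as a hypothesis. Such a loss would remove miR-491-5p as well. The highest miR-491-5p count in these 3 lines was 3 reads, but all 9 lines had 4 reads or fewer, so the test was void and the explanation stays open.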
